A study of Rattus norvegicus with 6 samples.

How the data were processed

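RNA from rat mesenchymal stem cells was measured in 6 poly(A) RNA-seq libraries, 3 labelled Dox and 3 labelled SMNV. Per the labels' protocols, the cells grew in high-glucose DMEM with 10% serum, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build mRatBN7.2, without roles or versions. Strandedness of the counting and the annotation release are not given in the sources used here. Without a stated strand, reads from a gene and an overlapping or antisense partner cannot be told apart.

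The authors deposited 2 tables for the series. The first holds estimated counts per gene, not normalized, per the file headers and the values: column totals ran from 18640909 to 21506967 and differed between libraries, and 17.9% to 18.8% of the values above 0 in each library had decimals. Decimals are not what plain counting of whole reads gives, and how the authors obtained them is not given in the sources used here. The second table holds TPM (length-scaled transcript abundances) as the authors computed them, with the same sum in each library. Both tables carry a gene length in bases, symbols, and annotation terms from the authors. The estimated counts were rounded to whole numbers before any count model. The design written before the data were examined assumed whole counts, and the test it named was kept. Every per-library column matched a labelled sample by name. Gene positions were not used here.

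The table had 30560 gene rows, of which 17484 had any count. Of all rows, 6514 lacked a symbol, and 612 of these received one through the Entrez number in the same row and an NCBI RefSeq table of the assembly GRCr8, which was used for names only. Among tested rows, 1009 still had no symbol. A row is named by its own symbol, and rows that share a symbol were tested as separate rows. Reads from near-identical copies, such as the alpha glutathione transferases, ribosomal protein genes with processed copies and histone genes, may have been divided between rows by the authors' counting, so single members of these families are less certain.

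Counts were compared with edgeR 4.0.16 in R 4.3.3. Rows passing filterByExpr for the 2 groups were kept, which left 12614 tested genes holding over 99.9% of the counts. Libraries were scaled with TMM factors, and a quasi-likelihood model with the group as its only term was fitted to all 6 libraries (glmQLFit, glmQLFTest). The test is two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. A positive log2 fold change means higher in SMNV. The standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. CPM are counts scaled to a common library size after TMM normalization (cpm in edgeR), computed here from the deposited counts and shown as mean ± SD. The words rose and fell are used for genes past the threshold.

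A collection of 29 gene lists was fixed before the data were examined. It holds 718 entries and 703 different genes, of which 582 were tested, and covers cell cycle, p53 targets, senescence, lineage, stress, metabolic and inflammatory themes together with markers of haematopoietic, endothelial and smooth muscle cells. Each list was tested with camera, which asks whether its genes rank differently from the other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 29 lists. The same test with an estimated correlation, and fry, which tests a list on its own, were alternatives. For each list the members rising and falling were counted with adjustment over all genes and adjusted over the list alone. Gene Ontology and pathway terms from the authors' table were tested with a one-sided hypergeometric test among rising and falling genes separately. Terms had 10 to 500 tested genes, the background was the tested genes with a term of that kind, and adjustment was within direction and kind. The terms of 749 tested genes were not used here, and 11119 tested genes had at least 1 Gene Ontology term.

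Genes named in the text followed a rule fixed before the data were examined. It took the 8 largest fold changes in each direction among changed genes with a mean of at least 5 CPM, a usable symbol and no overlap between the groups, up to 4 members of each list with the smallest p, the 5 smallest p-values of all genes, and a set of genes of interest whatever their value: Cdkn1a, Cdkn2a, Cdkn2b, Glb1, Lmnb1, Mki67, Il6, Runx2, Alpl, Bglap, Pparg, Hmox1 and Sirt1. Some list members are left out for lists that did not pass, and some genes that the rule takes are not reported here. Other genes are named with the remark that they were chosen after their values were seen.

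The libraries were compared in pairs by Pearson correlation of log2 CPM, by principal components and by a chi-square test of their counts, and no pair was alike enough to be a duplicate. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. The smallest two-sided p of an exact permutation test of 3 against 3 libraries is 0.1. The alternatives were median-ratio (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 with voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), no filter, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library, a threshold of 0.01, a test against a fold of 1.5, and for terms a background of all tested genes. Offsets that remove the trend with gene length, the summing of rows that share a symbol, and leaving out each library for terms were added after seeing the data.

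The edgeR step was tested on simulated counts for the 12614 genes of this comparison, drawn from the real means, dispersions and library sizes. It recovered 30% of 50 genes changed 1.25-fold, 54% of 50 changed 1.5-fold, 82% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 7 unchanged genes among its calls (5%). A planted list was found with 0 other lists called, and a planted term was found, with 3 other terms also called among 753. In the term check a random set of genes was raised besides the planted term. Whether the 3 other terms share genes with the planted term was not examined. In the gene test only the genes named above were changed, as many up as down, and each gene was drawn independently. In the real comparison 60.4% of genes changed, with 1094 higher and 192 lower above 2-fold, so these rates may not carry over. Without correlation between genes, the list check does not test the preset inter-gene correlation.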

Results

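Poly(A) RNA was sequenced from rat mesenchymal stem cells, multipotent stromal cells that can form bone, fat and cartilage cells, which had been exposed to 200 nM doxorubicin, a DNA-damaging anthracycline used to induce senescence, for 24 hours. Over the next 6 days in fresh medium the cells received vehicle (Dox, 3 libraries) or 100 µg/ml of a preparation called SMNV in the labels (SMNV, 3 libraries). The labels do not expand that name. No library from cells without doxorubicin was analysed here. The libraries held 18640909 to 21506967 estimated counts, and 15102 to 15347 genes had a count. Pearson correlations of log2 CPM were 0.989 to 0.992 within a group and 0.947 to 0.969 between the groups. The first principal component, 75.9% of the variance, separated the groups.

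The comparison of SMNV with Dox asks how expression in doxorubicin-treated cells differed with the preparation. In the SMNV libraries genes of mitosis rose together, p53 targets and DNA damage response genes mostly fell, and genes of the B-type lamins, type I collagen and elastin rose. Of 12614 tested genes, 7614 (60.4%) changed by edgeR's quasi-likelihood test, 3841 higher and 3773 lower. The changes were mostly small: 4496 (59.0%) of them were below 1.5-fold. Among changes above 2-fold, 1094 genes were higher and 192 lower. The CPM of the groups did not overlap for 66.9% of tested genes, where chance gives 10%.

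The split by direction differed on the authors' TPM values, where the test differed too. No TMM or other scaling factor was applied to TPM values, here or in any TPM result below. Scaling and test therefore changed together, and the values of single genes differed as well. With voom, a limma test on TMM-scaled counts, 50.6% of the changed genes were higher. With limma-trend on log2(TPM + 1), 39.8% of the changed genes were higher in place of 50.4% (51.1% and 51.2% with RLE and upper-quartile scaling of the counts), and the median log2 fold change of all tested genes moved from -0.01 to -0.10. Single genes moved by unlike amounts. Cdkn2b went from 0.02 to -0.30 and Glb1 from 0.04 to -0.09. The fall of Cbx5, chosen after its values were seen, became smaller, at -0.11. A scaling factor alone would move all genes by about the same amount. TPM results below therefore also carry gene-level differences between the 2 tables, whose source was not tested. The groups also differed in measures of the libraries themselves. A 28S ribosomal RNA row stood at 3.25 ± 2.41 CPM of the unscaled total in Dox and 66.4 ± 50.3 in SMNV, and the 10 most abundant genes took 14.4% to 15.2% of counts in Dox and 17.8% to 19.4% in SMNV (n = 3, exact permutation p = 0.1 for each, the smallest possible). Mitochondrial transcripts took 3.63 ± 0.402% and 3.39 ± 0.223% (n = 3, exact permutation p = 0.5).

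Every tested member of the G2/M and mitosis list rose: 29 of 29, over all genes and adjusted over the list alone, with a median log2 fold change of 1.30 and a range of 0.70 to 2.47. Cdc20, an activator of the anaphase-promoting complex, went from 29.4 ± 2.08 CPM in Dox to 163 ± 12.5 in SMNV (n = 3), a log2 fold change of 2.47 ± 0.08 (SE, adjusted p = 1.6e-11, edgeR). Plk1, the polo-like mitotic kinase, rose by 2.47 ± 0.08, the mitotic cyclin Ccnb2 by 1.95 ± 0.08, the mitotic kinesin Kif20a by 1.58 ± 0.06 and the proliferation marker Mki67 by 0.79 ± 0.07. The list passed camera with an adjusted p of 1.3e-56, and of 0.00158 with an estimated correlation. Of 29 tested genes of S phase and DNA replication, 16 rose, 3 fell and 10 did not pass; adjusted over the list alone, 17 rose and 3 fell. The thymidine kinase gene Tk1 rose from 47.7 ± 3.80 to 113 ± 4.18 CPM (n = 3), the replicative helicase subunit Mcm2 by 0.85 ± 0.07, the flap endonuclease Fen1 by 0.93 ± 0.09 and the ligase Lig1 by 0.59 ± 0.06. Cdc6, Ccne2 and Prim1, named after their values were seen, fell by 0.73, 0.62 and 0.20 on the log2 scale, and Prim1 lost its call in 4 of the 6 fits without a library (Dox 1 or 3, SMNV 1 or 3). The S-phase list passed at an adjusted p of 0.0440 (0.589 with an estimated correlation) and did not pass without Dox 2 (0.0695) or SMNV 2 (0.0847) or on TPM values (0.0619).

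Among 29 tested p53 targets and DNA damage response genes, 17 fell, 4 rose and 8 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of -0.56. Cyclin G1, encoded by Ccng1, went from 460 ± 41.1 to 94.6 ± 5.11 CPM (n = 3), a log2 fold change of -2.28 ± 0.08 (SE, adjusted p = 1.6e-11, edgeR). Mdm2, a ubiquitin ligase gene, changed by -1.94 ± 0.07, the ectodysplasin receptor gene Eda2r by -2.85 ± 0.14 and Zmat3, an RNA-binding p53 target, by -1.44 ± 0.07. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 94.2 ± 6.66 to 37.2 ± 3.38 CPM (n = 3), a log2 fold change of -1.34 ± 0.08. The risers, named after their values were seen, were Bbc3 (1.68 ± 0.23), Ninj1 (0.98 ± 0.12), Gadd45a (0.49 ± 0.06) and Sesn2 (0.25 ± 0.07), and Sesn2 lost its call on the TPM scale. The list passed camera at an adjusted p of 4.4e-08, and of 0.0499 with an estimated correlation.

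**Figure D1:**
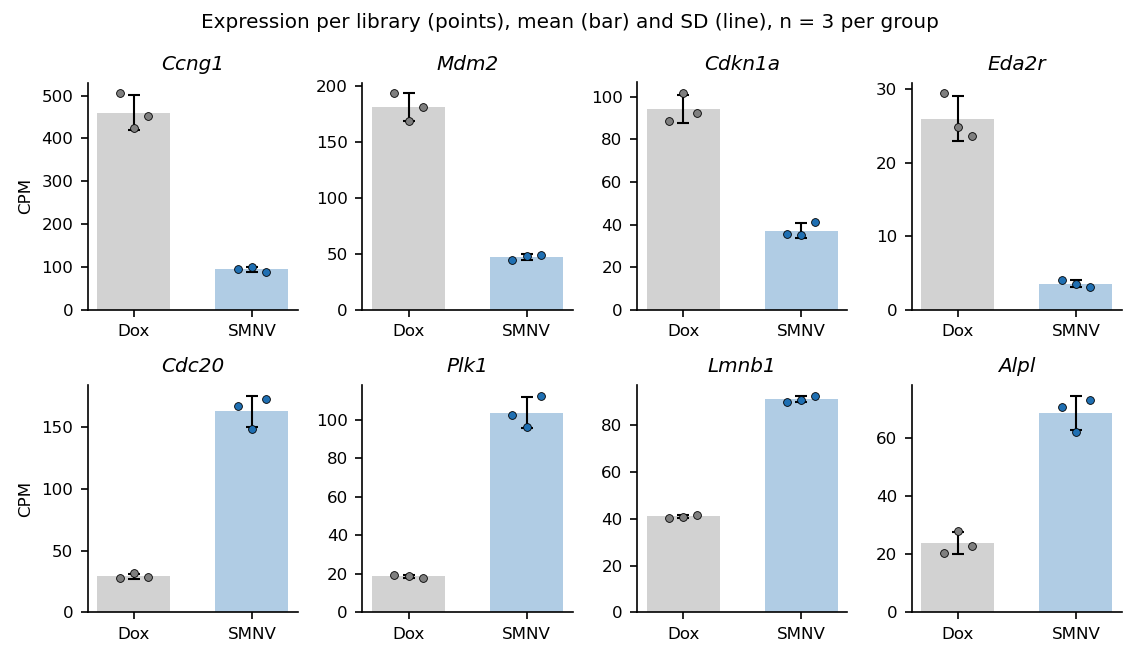
CPM, counts scaled to library size, in each library (points), with the group mean (bar) and SD (line), for 4 p53 targets in the upper row and for Cdc20, Plk1, Lmnb1 and Alpl in the lower row, with 3 libraries per group and a linear axis from 0 in every panel. The groups do not overlap in any panel: Ccng1 averaged 460 CPM in Dox and 94.6 in SMNV, and Cdc20 29.4 and 163.

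Other markers used in studies of senescence moved in different directions. Lmnb1, the lamin whose loss marks many senescent cells, went from 41.0 ± 0.628 to 91.2 ± 1.33 CPM (n = 3), a log2 fold change of 1.15 ± 0.07. Cdkn2a, whose row covers the locus of p16 and p19Arf, also rose, by 2.22 ± 0.33, from 0.752 ± 0.341 to 3.54 ± 0.932 CPM (n = 3). Cdkn2b, encoding the related inhibitor p15, had a log2 fold change of 0.02 ± 0.10 (adjusted p = 0.89), and on the TPM scale it was lower, at -0.30 (adjusted p = 0.0219, limma). Glb1, which encodes the lysosomal beta-galactosidase, had a log2 fold change of 0.04 ± 0.06 (adjusted p = 0.63) and of -0.09 on the TPM scale (adjusted p = 0.18, limma). Of 20 tested genes of the senescence-associated secretory phenotype, 7 rose and 9 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.75). Within it the insulin-like growth factor binding proteins Igfbp6, Igfbp3 and Igfbp4 rose by 1.90 ± 0.14, 1.42 ± 0.11 and 1.17 ± 0.08. The chemokine gene Ccl2 fell from 6.98 ± 1.21 to 1.53 ± 0.565 CPM (n = 3). The other 17 genes of the list, Il6 among them, were below the filter, at no more than 0.644 CPM of the unscaled total in any library. The counts above therefore do not cover them.

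Of 14 tested genes in the list of chromatin and lamina genes lost in senescence, 8 rose, 3 fell and 3 did not pass. The counts were the same adjusted over the list alone. The name was fixed with the list, and whether each member declines in senescence was not tested here. The B-type lamin gene Lmnb2 rose by 2.12 ± 0.11, the histone variant gene H2az1 by 1.90 ± 0.08 and the nucleosome-binding protein gene Hmgn2 by 0.92 ± 0.06. Hmgb1, Cbx5 and Supt16h, named after their values were seen, fell by 0.30, 0.27 and 0.23 on the log2 scale. The list passed at an adjusted p of 3.8e-04, and its adjusted p was 0.331 with an estimated correlation. On the TPM scales the list did not pass (0.0619 and 0.0655). The fall of Cbx5 lost its call on the TPM scale, that of Hmgb1 without Dox 1, SMNV 2 or SMNV 3, and that of Supt16h without SMNV 3. Among 44 tested DNA and histone modifying enzymes, 23 rose and 13 fell (24 and 13 adjusted over the list alone), and the list did not pass (adjusted p = 0.11), though it passed without a filter (0.0282) and with length-corrected offsets (0.0212). The histone H3 lysine 9 methyltransferase gene Ehmt2 rose by 1.75 ± 0.11, the deacetylase genes Sirt6 and Hdac7 by 1.83 ± 0.15 and 1.30 ± 0.11, and the demethylase gene Kdm4b by 1.03 ± 0.10. Sirt1, another deacetylase gene, fell by 0.55 on the log2 scale.

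Transcripts of type I collagen and elastin were higher in SMNV. Of 29 tested genes of fibrillar matrix and crosslinking, 16 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. Col1a2, a chain of type I collagen, went from 16519 ± 1517 to 33523 ± 3481 CPM (n = 3), a log2 fold change of 1.02 ± 0.09, and Col1a1, the other chain, rose by 1.08 ± 0.10. Together the pair took 3.68 ± 0.360% of counts in Dox and 7.32 ± 0.766% in SMNV (n = 3, exact permutation p = 0.1, the smallest possible). The elastin gene Eln rose by 3.01 ± 0.25 from a mean of 0.843 CPM, the crosslinking enzyme gene Loxl1 by 1.42 ± 0.09 and the fibulin gene Fbln1 by 1.41 ± 0.09. Tnc, Lum, Thbs1 and Postn, named after their values were seen, fell by 0.59, 0.34, 0.24 and 0.22, and Postn lost its call without SMNV 3. The list passed at an adjusted p of 0.00435, and its adjusted p was 0.627 with an estimated correlation. It did not pass on TPM values (0.0619).

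Osteoblast genes did not pass as a group: of 15 tested, 5 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.87). Their median log2 fold change was -0.02, their mean 0.15, and the test pointed up. Alpl, encoding the alkaline phosphatase of mineralizing cells, went from 23.9 ± 3.90 to 68.8 ± 5.82 CPM (n = 3), a log2 fold change of 1.53 ± 0.11 (SE, adjusted p = 2.6e-08, edgeR). Enpp1, which produces the mineralization inhibitor pyrophosphate, fell by 0.81 on the log2 scale, and osteopontin, encoded by Spp1, fell by 0.57. Runx2, the osteoblast transcription factor, had a log2 fold change of -0.06 ± 0.07 (adjusted p = 0.50), and osteocalcin, encoded by Bglap, had no counts. Bglap was among 10 osteoblast genes below the filter, at no more than 0.376 CPM of the unscaled total in any library. Of 16 tested adipocyte genes, 9 rose and 2 fell, with the same counts adjusted over the list alone (list adjusted p = 0.080, and 0.0282 without a filter). Klf15 rose by 1.93 ± 0.13, the fatty acid synthase gene Fasn by 0.84 ± 0.09 and the lipoprotein gene Apoe from 2.55 ± 0.353 to 7.18 ± 0.361 CPM (n = 3), while Pparg, the master regulator, stayed below 1 CPM with a log2 fold change of 0.25 ± 0.40 (adjusted p = 0.60). Mesenchymal stromal cell surface markers passed as lower at an adjusted p of 0.0460 (0.331 with an estimated correlation), with 7 of 14 lower, 3 higher and 4 not passing, the same adjusted over the list alone. The hyaluronan receptor gene Cd44 fell by 1.08 on the log2 scale, Itgb1 by 0.64, Cd9 by 0.56 and the intermediate filament gene Nes by 0.46. Pdgfrb, Eng and Cspg4, named after their values were seen, were higher by 0.31, 0.31 and 0.23; Eng and Cspg4 lost their calls on TPM values, and Cspg4 also without Dox 1, Dox 3, SMNV 1 or SMNV 3. Leaving out any library except Dox 1 ended the list's call (adjusted p 0.0513 to 0.0782), as did TPM values (0.166).

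Ribosomal protein and cholesterol synthesis genes also passed as higher. Of 32 tested cytosolic ribosomal protein genes, 17 rose, 9 fell and 6 did not pass, the same adjusted over the list alone. Rps15 rose by 1.83 ± 0.10, and the stalk proteins Rplp1, Rplp2 and Rplp0 by 1.74 ± 0.11, 1.66 ± 0.09 and 1.18 ± 0.08. These were the same libraries in which the 28S row was higher. The list passed at an adjusted p of 0.00614, and its adjusted p was 0.881 with an estimated correlation; it did not pass with voom (0.0855), on TPM values (0.209) or with length-corrected offsets chosen after seeing the data (0.165). Of 24 tested genes of cholesterol synthesis and uptake, 14 rose, 3 fell and 7 did not pass, the same adjusted over the list alone. Mevalonate kinase Mvk rose by 1.49 ± 0.12, the decarboxylase gene Mvd by 1.39 ± 0.14, the regulator Srebf2 by 1.05 ± 0.10 and its retention factor Insig1 by 0.50 ± 0.06. Msmo1, Idi1 and Nsdhl, named after their values were seen, fell by 0.29, 0.29 and 0.23, and Idi1 lost its call without Dox 1 or SMNV 2. The list's adjusted p was 0.0440, 0.331 with an estimated correlation, 0.0507 without Dox 3, 0.0654 without SMNV 2 and 0.0619 on TPM values.

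Abcb1b and 2 glutathione transferase genes were among the 8 largest falls of genes with a mean of at least 5 CPM, a usable symbol and no overlap between the groups. Abcb1b, a P-glycoprotein drug efflux pump whose substrates include doxorubicin, went from 128 ± 5.89 to 12.2 ± 0.596 CPM (n = 3), a log2 fold change of -3.40 ± 0.08 (SE, adjusted p = 4.2e-13, edgeR). It had the smallest p of all genes. A second row under the same symbol, at 3.44 and 3.71 CPM, did not pass (adjusted p = 0.65), and the sum of both rows changed by -3.05. The glutathione transferase genes Gsta5 and Gsta2 changed by -3.27 ± 0.20 and -2.71 ± 0.23, and the activin antagonist Fst by -2.68 ± 0.08. Tspyl1 changed by -1.98 ± 0.29 in the row with 8.55 CPM in Dox, while a row of the same symbol with 55.5 CPM had a log2 fold change of -0.19 (adjusted p = 0.080), and the sum changed by -0.34. The small GTPase gene Rab1b changed by -2.80 ± 0.27. The Rab1b value belongs to 1 of 2 rows with that symbol, and the sum of both rows had a log2 fold change of -0.04 (adjusted p = 0.65). Under the same limits the 8 largest rises were in Mxd3, a repressor of the MYC network (3.76 ± 0.21), Ankle1 (3.47 ± 0.23), the respiratory complex III subunit gene Uqcrq (2.97 ± 0.25), the homeobox gene Pitx1 (2.97 ± 0.23), the cytokine gene Mif (2.83 ± 0.28), Mex3d (2.77 ± 0.25), Arhgef39 (2.75 ± 0.13) and the mitotic kinesin Kifc1 (2.62 ± 0.09). Among the SMNV libraries all 8 were lowest in SMNV 2, by unlike amounts. Uqcrq had 16.7 CPM there against 33.5 in SMNV 1 and 35.1 in SMNV 3. Mif had 11.8 against 19.7 and 30.5, and Kifc1 81.5 against 91.3 and 91.4. Pimreg, a regulator of mitosis, was among the 5 smallest p-values, at 2.59 ± 0.08.

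Of 23 tested NRF2 antioxidant genes, 10 fell and 5 rose, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.080), though it passed without a filter (0.0464) and with length-corrected offsets (0.0155). The quinone reductase gene Nqo1 fell by 1.41 and the glutathione transferase gene Gsta1 by 1.27 on the log2 scale, while the heme oxygenase gene Hmox1 rose by 1.16 ± 0.09 and the ferritin gene Ftl1 by 1.23 ± 0.09. Among glycolysis genes 9 of 22 rose and 6 fell (list adjusted p = 0.77). Slc2a3, Pgk1 and Ldha, encoding a glucose transporter and glycolytic enzymes, fell by 0.97, 0.71 and 0.67, and the phosphofructokinase gene Pfkl rose by 1.26 ± 0.11. The tricarboxylic acid cycle list had 7 of 24 higher and 11 lower (0.75), nuclear-encoded oxidative phosphorylation 14 of 36 higher and 10 lower (0.61), and mitochondrially encoded transcripts 7 of 13 higher and 4 lower (0.80). Oxidative phosphorylation had a median of -0.05 but a mean of 0.24 and a test pointing up, and glycolysis a median of 0.05 and a mean of 0.06 with a test pointing down. For each of these 4 metabolic lists the counts were the same adjusted over the list alone.

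The other lists did not pass. Inflammatory and immune lists had 10 of 20 NF-kB targets higher and 4 lower (adjusted p = 0.75), 9 of 15 genes of MHC class I and antigen processing higher and 2 lower (0.23), and 3 of 18 interferon response genes higher and 3 lower (0.87). TGF-beta targets had 9 of 20 higher and 5 lower (0.52), lysosome and autophagy genes 10 of 30 higher and 9 lower (0.72), and cytosolic heat shock genes 4 of 15 higher and 8 lower (0.54). Smooth muscle and myofibroblast genes had 6 of 15 higher and 3 lower (0.68), and chondrocyte genes 5 of 8 higher and 1 lower (0.72). The other 11 chondrocyte genes were below the filter. Of markers of other cell types, 4 haematopoietic and macrophage genes were tested, 1 higher and 1 lower (0.91), and 3 endothelial genes, 1 higher and 1 lower (0.85). The other 18 and 12 markers stayed at or below 0.570 and 0.697 CPM of the unscaled total in every library or had no row. The heat shock list had a median of -0.21 and a mean of 0.01, and the haematopoietic list a median of 0.25 and a mean of 0.06 with a test pointing down. Adjusted over the list alone, the counts differed for TGF-beta targets (10 higher) and interferon response genes (2 lower) and were the same for the rest of this group.

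**Figure D2:**
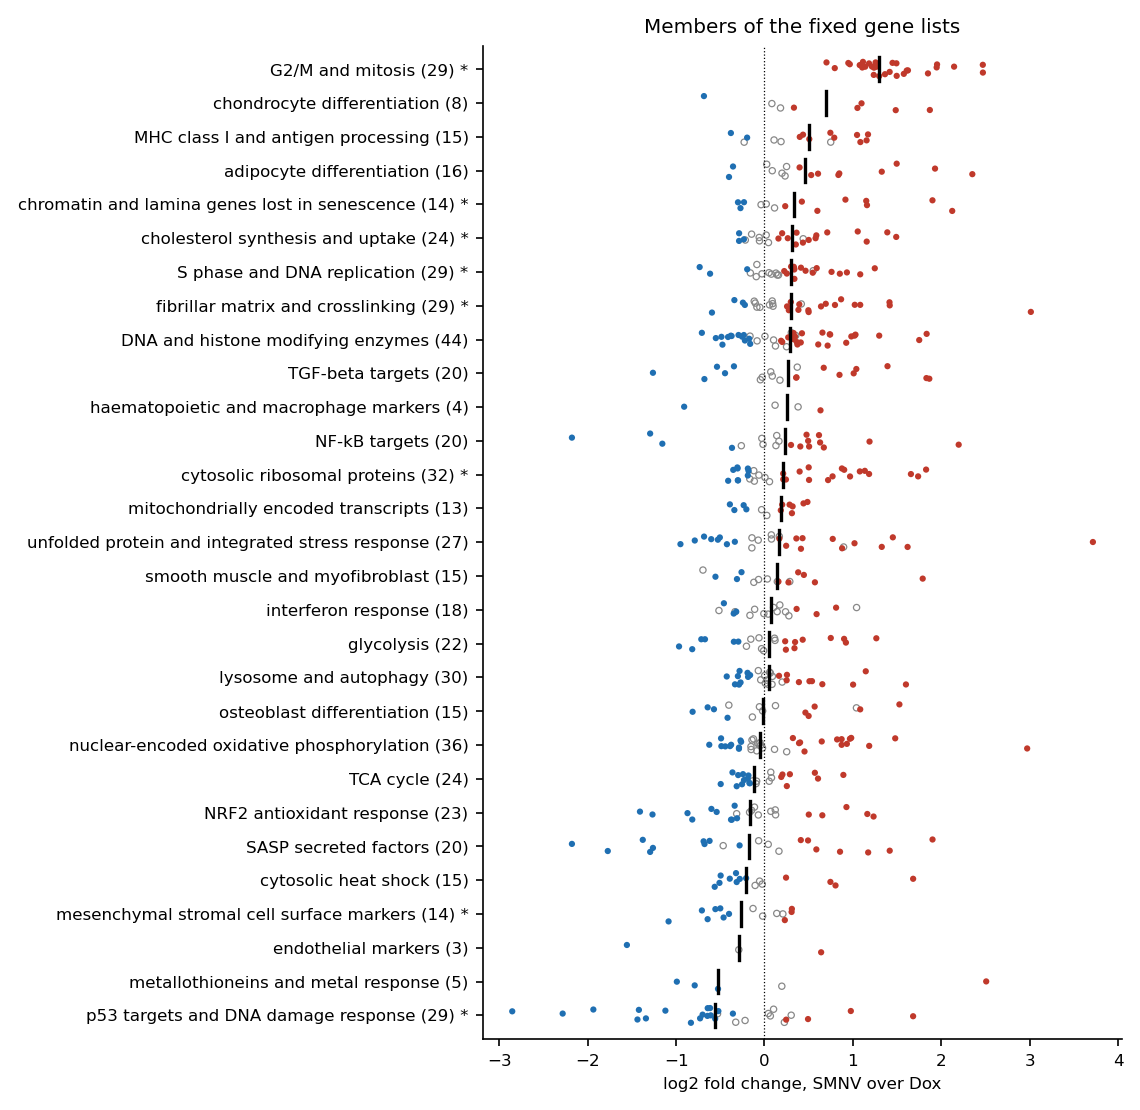
Log2 fold change (SMNV over Dox, horizontal axis) of each tested member of the 29 fixed gene lists (number tested in brackets), with red and blue points for members that rose or fell at an adjusted p below 0.05, open points for the others, black bars for list medians and an asterisk for lists that passed camera. The G2/M list lies wholly above 0, from 0.70 to 2.47, and the p53 list has its median at -0.56.

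Annotation terms of mitosis and matrix were also enriched. Of terms tested, 17 were enriched among risers and 4 among fallers by the hypergeometric test. Chromosome segregation had 26 of 35 tested genes higher (adjusted p = 2.4e-04), mitotic chromosome condensation 12 of 12 (4.1e-04), cell division 49 of 88 (7.9e-04) and extracellular matrix organization 35 of 58 (0.00137). Structural constituents of the ribosome had 99 of 227 higher (0.00549). Among fallers were protein folding with 33 of 60 genes (0.0280), the endoplasmic reticulum with 163 of 425 (0.00795), the pathway of protein processing in the endoplasmic reticulum with 54 of 107 (0.0104) and regulation of DNA-templated transcription with 164 of 410 (0.0195).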

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

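Length-corrected offsets, summed rows and leaving out libraries for terms were chosen after seeing the data; the rest was planned. With other scalings, tests and filters 7255 to 7730 genes changed, 7773 with length-corrected offsets and 7589 with rows sharing a symbol summed, 6635 to 7454 without each library, and 6037 at an adjusted p under 0.01. Tested against a 1.5-fold change, 1580 genes passed, 1346 higher and 234 lower. DESeq2 shared 95.1% of the edgeR calls in the same direction and log2(TPM + 1) 88.2%, with 11 opposite calls (1 with rows summed). On log2(TPM + 0.1), also with 11 opposite calls, 39.8% of 7688 changed genes were higher and the median log2 fold change was -0.12. The labels state no pairing of the replicate numbers. Deviations of same-numbered libraries correlated at 0.008, -0.116 and 0.002. Dox 1 and Dox 2 correlated best with SMNV 2 (0.118) and SMNV 3 (0.138), and Dox 1 with SMNV 3 gave -0.132. With 3 libraries per group these values neither show nor exclude a pairing. With a replicate block 7387 genes changed and 5 lists passed, and Prim1 (adjusted p = 0.0524) and Cspg4 (0.0596) lost their calls. Genes changed only slightly are limited by depth and replicates.

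The list tests also moved; the cause was not tested. Of 29 lists, 8 passed with the preset correlation, 5 with a filter of 1 CPM, 5 (without SMNV 2) to 8 without each library, 11 without a filter, 2 on log2(TPM + 1), 2 on log2(TPM + 0.1), 2 with an estimated correlation and 21 with fry, which does not compare a list with other genes. The G2/M and p53 lists passed in every fit run. On log2(TPM + 1) the adjusted p was 0.0619 for S phase, fibrillar matrix, cholesterol and chromatin and lamina, 0.166 for surface markers and 0.209 for ribosomal proteins. On log2(TPM + 0.1) it was 0.0634 for S phase, fibrillar matrix and cholesterol, 0.0655 for chromatin and lamina, 0.176 for surface markers and 0.218 for ribosomal proteins. With an estimated correlation it was 0.589 for S phase, 0.331 for surface markers, cholesterol and chromatin and lamina, 0.627 for fibrillar matrix and 0.881 for ribosomal proteins. With the filter of 1 CPM it was 0.0520 for S phase and cholesterol and 0.0524 for surface markers, and with the block 0.0515 for all 3, which does not measure a weaker effect. Surface markers also lost the call with upper-quartile factors (0.0503), voom (0.136) and length-corrected offsets (0.0726), and ribosomal proteins with voom (0.0855) and length-corrected offsets (0.165). Calls were gained with length-corrected offsets by NRF2 genes (0.0155) and DNA and histone modifying enzymes (0.0212), and without a filter by these (0.0464 and 0.0282) and adipocyte genes (0.0282). Without each library in turn, the adjusted p ran from 0.0197 to 0.0847 for S phase, 0.0197 to 0.0654 for cholesterol and 0.0197 to 0.0782 for surface markers.

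Among lists and named genes, directions turned only for those that had not passed. The haematopoietic list turned with voom (adjusted p = 0.952), both TPM scales (0.918 and 0.949), fry (0.760) and without Dox 2 (0.961; 0.892 to 0.989 without each library), the endothelial list with the filter of 1 CPM (0.893) and on log2(TPM + 1) (0.918), glycolysis on log2(TPM + 0.1) (0.984), oxidative phosphorylation with length-corrected offsets (0.889), and mitochondrial transcripts with those offsets (0.634) and without Dox 2 (0.961; 0.459 to 0.973 without each library). Cdkn2b turned to -0.30 and -0.32 on the TPM scales, -0.023 with length-corrected offsets, and ran from -0.055 (without SMNV 3) to 0.080 (without Dox 1). Glb1 turned to -0.095 and -0.096 on the TPM scales, and Runx2 to 0.018 with length-corrected offsets. Of the 110 named and tested genes, 97 kept their direction and side of the threshold throughout. The others include Rab1b, at -0.04 with its rows summed.

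Enriched terms numbered 21, 28 with genes at an adjusted p of 0.01, and 34 with all tested genes as background (30 among risers). The larger background counts genes without terms. Without each library they numbered 20 to 31, and 7 of those among fallers, in place of 4, without Dox 2, Dox 3 or SMNV 3.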

Other observations

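The tests on gene length as a reason for the list results, on S-phase against G2/M genes and on summed rows were chosen after the results were seen; the tests on replicate differences and on other splits of the libraries were written down before their results.

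Members of the list of unfolded protein and integrated stress response genes went in both directions, and the list did not pass (adjusted p = 0.75, 12 of 27 higher and 8 lower, and 14 and 9 adjusted over the list alone). The serine synthesis gene Phgdh rose by 1.45 ± 0.09, the mitochondrial serine enzyme gene Shmt2 by 1.02 ± 0.09 and the stress-induced pseudokinase gene Trib3 by 1.62 ± 0.13, while Edem1, which acts in degradation of misfolded glycoproteins, changed by -0.79 ± 0.06 (log2, SE, edgeR). Among members chosen after their values were seen, the chaperone gene Hspa5 went from 991 ± 63.8 to 617 ± 5.81 CPM (n = 3) and Manf changed by -0.95 ± 0.10, while Ddit3 and Chac1, which respond to the integrated stress response, rose by 0.77 ± 0.10 and 0.88 ± 0.09. In the list of metal-handling genes, the metallothionein gene Mt2A rose from 1.80 ± 0.196 to 10.3 ± 0.693 CPM (n = 3), and the transferrin receptor gene Tfrc and the zinc transporter genes Slc30a1 and Slc39a10 changed by -0.99 ± 0.11, -0.79 ± 0.12 and -0.53 ± 0.09. That list had 1 of 5 higher and 3 lower (2 and 3 adjusted over the list alone) and did not pass (adjusted p = 0.75); its median was -0.53 and its mean 0.08.

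The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split changed 7614 genes, passed 8 lists and enriched 21 terms, and 1 of the 10 splits, the real one, reached each of these. The highest of the other splits gave 0 genes, 6 lists and 0 terms. Each of them mixes the groups, so the group difference becomes spread within each side. Their 0 genes and 0 terms therefore do not measure chance. Every one of them passed at least 1 list with 0 genes changed. Part of the group difference remains between the sides of a mixed split, so these list passes do not measure chance either.

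The joint rise of G2/M genes and fall of p53 targets was set against several explanations. Long genes had lower fold changes across genes (Spearman rho -0.17 for 10072 genes of at least 5 CPM), but offsets that removed this trend left 99.9% of the G2/M median and 114% of the p53 median, with adjusted p of 6.5e-59 and 1.9e-08. A gene axis averaged from SMNV 3 minus SMNV 2 and Dox 2 minus Dox 1, each scaled to the group difference, gave -8.91% of the G2/M median (95% bootstrap bounds -18.1 to 6.06). For the p53 median it gave 8.28% (-39.2 to 44.9). Both lay below a bound of 50% written before the values were seen. Under the 20% of an earlier plan the p53 part would be undecided. The 2 differences correlated with each other only at r = 0.25 across genes. Before scaling, the medians along the SMNV and Dox differences were -0.02 and -0.07 for G2/M, and -0.003 and -0.09 for p53. Neither difference was tested alone. The G2/M median lay 0.996 above the S-phase median (bounds over list members 0.880 to 1.29), so these sets did not rise by the same amount. Both medians were known when this comparison was chosen, and how far more cycling cells would raise each set was not measured. The comparison therefore decides nothing about more cycling cells in SMNV, which stay open. No other biological explanation was tested. An action of SMNV and an unequal dose or retention of doxorubicin between the arms also stay open, since libraries without doxorubicin or with SMNV alone were not analysed here.

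Differences between replicates ran partly along the difference between the groups. Across genes, which are not independent replicates, SMNV 3 minus SMNV 2 correlated with SMNV 1 minus the Dox mean at r = 0.44 (rho 0.38), and Dox 2 minus Dox 1 with the SMNV mean minus Dox 3 at r = 0.48 (rho 0.56); these pairs had been noticed before the test was written and were the largest in each group among 6, whose r ran from 0.10 to 0.48. Genes of at least 50 CPM gave 116% of these 2 correlations on average (of the other pairs, SMNV 1 minus SMNV 2 fell from 0.102 to 0.054 and 3 rose). The differences in a pair share no library, so independent counting noise would not align them, and the 116% decides nothing about such noise. Removing the length trend left 100.4% of the 2 correlations, though the replicate differences of those pairs had little trend to remove (rho 0.067 and -0.057). In the pairs with more (rho 0.398 and -0.375) r moved from 0.102 to 0.175 and from 0.339 to 0.293. That argues against length as the whole cause but not against a part in some pairs. Among lists that passed, the averaged axis gave 60.0% of the median of the ribosomal protein list and 38.3% of that of the fibrillar matrix list. For the others it gave -13.7% to 8.28%. Before scaling, the ribosomal medians had opposite signs along SMNV 3 minus SMNV 2 (-0.10) and Dox 2 minus Dox 1 (0.27). The bounds on the log2 scale reached past the whole median for surface markers (-0.38, median -0.27), cholesterol (0.40, median 0.31) and ribosomal proteins (0.24, median 0.21). For chromatin and lamina (0.20, median 0.33) and fibrillar matrix (0.22, median 0.30) they reached past 50% of it. None of these lists is therefore shown to be free of the axis. A graded response of the cultures and a technical difference that also varies between replicates, such as base composition, stay open; base composition was not tested here.

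Some large fold changes belonged to 1 of several rows of a gene. The falling Rab1b row (ENSRNOG00000050510) went from 58.9 ± 6.44 to 8.39 ± 5.45 CPM while the other (ENSRNOG00000070897) went from 34.5 ± 6.20 to 82.7 ± 5.46 (n = 3), and the log2 ratio of their sum was -0.0363 ± 0.0552 (SE), so reads divided differently between the rows are a candidate explanation. A row without a deposited symbol that the authors match to the major prion protein (ENSRNOG00000070982) had 783 to 1515 counts in Dox and 2 to 8 in SMNV, and the row of Prnp itself also fell, by 0.30 on the log2 scale. The log2 ratio of their sum was -0.522 ± 0.0448 (SE), which argues against reads that only moved between the rows, since that would keep the sum and raise the Prnp row; a shift of reads within a lower total stays open. Of 75 symbols with several tested rows, 8 had rows called in opposite directions, and 13.7 would be expected if 2 rows per symbol moved independently.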
